A study of Mus musculus with 4 samples.

How the data were processed

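Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map RUVBL2, an AAA+ ATPase found in several chromatin remodelling and chaperone complexes, in the hypothalamus of wild-type male mice aged 8 weeks. Per the labels' protocols, tissue was fixed in 1% formaldehyde for 10 min, chromatin was pulled down with an antibody against RUVBL2 on magnetic beads, and libraries of pulled-down and input DNA were amplified for 15 cycles and read as pairs of 150 bp. The series holds 4 libraries in 2 groups, with 2 RUVBL2 ChIP libraries and 2 input libraries. Each group carries the numbers 1 and 2, taken from the titles. The labels do not say whether the 2 numbers stand for separate animals or pools, so the agreement between the replicates may be technical in part.

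The values analysed were 2 peak lists and 2 summit lists, 1 of each per ChIP library; peaks were therefore called per library and not on pooled reads. No separate values of the input libraries were used here. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie2 2.3.4.1, MACS2 2.1.0 and ChIPseeker, and the build GRCm38; the settings of these tools and the control given to the peak caller are not given in the sources used here. In the deposited peak lists, each peak has a fold enrichment over the background that the authors' peak caller estimated, a −log10 p and a −log10 q at its summit. The deposited score column equals 10 times the −log10 q, cut to a whole number. The lowest deposited −log10 q was 1.32 in replicate 1 and 1.34 in replicate 2. Fold enrichments and −log10 p are therefore the authors' values for each peak; they were used within a list only, the fold to describe peaks, the −log10 p to rank them, and both together to recover summit pileups and backgrounds. The peak names of replicate 2 begin with Hyp3 although its title begins with Hyp2; the list was assigned by its GEO sample. The summit lists repeated the summit positions and the −log10 q of the peak lists.

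The total read number of each library is not given in the sources used here, so depth was taken from the peaks themselves. The fold and the −log10 p of a peak are both functions of the summit pileup and of the background, the fold with 1 added to each, so the pair could be solved for both. In both lists a whole-number pileup matched 100% of peaks within a relative tolerance of 0.0001 on the −log10 p. On 1996 simulated peaks, the same step recovered 100% of the pileups exactly. The 95% intervals given with fold enrichments are exact Poisson intervals of the summit pileup with the background held fixed. They cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

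Shared regions were the joined intervals of peaks of both lists that overlapped by at least 1 bp. Genes came from a RefSeq gene table of GRCm38.p6, the build the files use, with 49603 gene rows on the assembled chromosomes, of which 21779 are protein-coding. A further 340 rows with coordinates inside the first 3 Mb of a chromosome other than Y, which is a gap in this build, were taken to lie on separate scaffolds and left out. The table gives the 2 ends of each gene but neither strand nor exons. The planned promoter window was therefore set around both gene ends, and a transcription start was not told apart from the other end of a gene. Exons, introns and UTRs were not assigned. The planned tests of base composition and of motifs were not run, because no genome sequence was used here. Random positions were drawn between the first and the last annotated gene of a chromosome, since gap positions were not used.

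Overlap between the lists and the position of shared regions were compared with 10000 random placements of the same peaks or regions within their chromosomes. The smallest p these can give is 0.0001 one-sided and 0.0002 two-sided. For 14 gene lists of 367 genes in all, and for 2 lists taken by symbol pattern (olfactory receptors and replication-dependent histones), the share of genes with the midpoint of a shared region within 3 kb of either gene end was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. Bodies of the same genes, widened by 3 kb on each side, were compared with the random placements, which keeps gene length but not the place of regions at gene ends. Homer1 is in 2 lists. Shares carry exact Clopper-Pearson 95% intervals. For a share of 0, the text gives as its limit 3 counts of the total, an approximate one-sided 95% bound that lies below the upper end of the two-sided exact interval drawn for the same list. The named genes were, by rule, the 20 shared regions with the best worst-case rank by −log10 p in the 2 lists, up to 4 genes per list, and 11 genes of interest whether or not they held a peak. Other list members named beside a count, and Lars2, were chosen after their values were seen. Some genes that the rule names are not reported here. The lists, the tests, the naming rule and most alternatives were fixed before the data were examined.

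On simulated data with the 21779 real genes, the list test called a planted list of 40 genes with a 50% share in 98% of 50 data sets, and called 2 of 750 unchanged lists. The placement test of overlap gave a p under 0.05 for 24 of 400 unrelated lists of 3941 peaks. The gene body test called the planted list in 10 of 10 data sets and 0 of 150 unchanged lists. In both placement simulations the unrelated peaks or regions were drawn uniformly, as in the placements themselves. They check the computation and do not measure how often peaks gathered at gene ends would be called. Alternatives covered a −log10 q of at least 5, the top 1000 peaks of each list, overlap of 50% of the shorter peak, summits within 250 bp, placement within 50 kb, a window of 1 kb, the ends of all annotated genes, the union of the lists and each list alone. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.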

Results

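RUVBL2 binding was measured by ChIP-seq in the hypothalamus of wild-type mice, the brain region that holds the neurons controlling appetite. The series title places the question in RUVBL2 neurons of the paraventricular nucleus, appetite and excitatory synaptic transmission. Replicate 1 gave 3943 peaks and replicate 2 gave 6403 peaks, with median widths of 415 and 521 bp. The median fold enrichment over background, as given by the authors' peak caller, was 4.93 in replicate 1 and 4.74 in replicate 2. The median summit pileup recovered from these values was 16 reads in replicate 1 and 22 in replicate 2, so a typical peak rested on few reads: the exact Poisson 95% interval of a pileup of 16 runs from 9.15 to 26.0. Overlapping peaks of the 2 lists formed 3111 shared regions, on which the comparisons below rest unless a library is named.

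Most shared regions lay at the ends of protein-coding genes. Of the 3111 regions, 2784 (89.5%, 95% interval 88.4 to 90.5) had their midpoint within 3 kb of a protein-coding gene end, against 8.78% ± 0.511 (SD over 10000 random placements; two-sided permutation p = 0.0002 from the placements, the smallest these can give). A further 245 regions (7.88%) lay in the interior of a protein-coding gene, where random placement put 36.8%, and 81 (2.60%) lay outside such genes, where it put 54.4%; both differed from placement with a two-sided p of 0.0002. The remaining region lay on an unplaced scaffold and was in none of these classes. The median distance from a region to the nearest gene end was 236 bp. The shares near a gene end were 88.8% in replicate 1 and 87.4% in replicate 2 taken alone. Among genes longer than 10 kb, 2545 held a shared region at one end only and 49 at both ends, where independent ends would give 125. In all, 3483 of 21779 protein-coding genes (15.99%) had a shared region within 3 kb of an end; a region between close neighbours was counted for both. When regions were moved at random by up to 50 kb, 24.4% fell near a gene end.

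**Figure D1:**
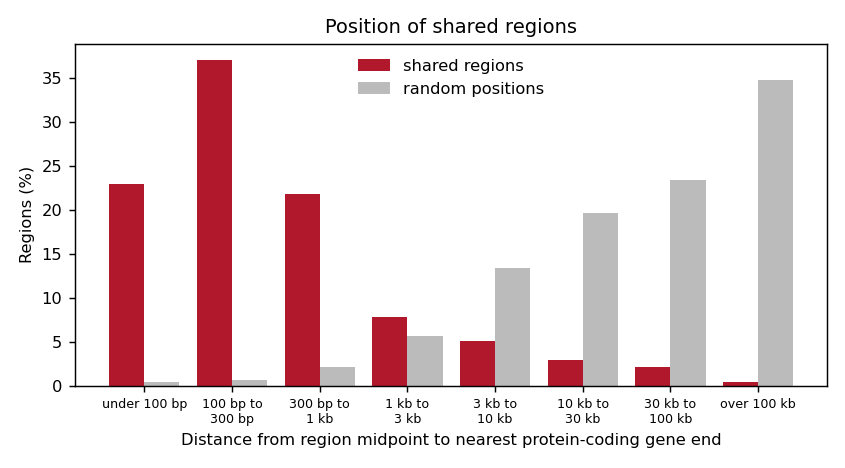
Share of the 3111 shared RUVBL2 regions (red bars) and of random positions on the same chromosomes (grey bars), in percent, by distance from the region midpoint to the nearest protein-coding gene end. Distances under 100 bp hold 23.0% of shared regions and 0.362% of random positions, and distances of 100 to 300 bp hold 37.0% and 0.651%.

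Among the 20 shared regions with the best rank in both lists were those at the histone methyltransferase genes Kmt2a and Kmt5b and their relative Kmt2e, at Srcap and Epc1, which encode subunits of remodelling and acetyltransferase complexes that contain RUVBL proteins, and at Nfyc, a subunit of the CCAAT-binding factor NF-Y. The region in Kmt2e (GRCm38 chromosome 5, 23432684 to 23434666), 639 bp from the gene end, had a fold enrichment of 13.4 (95% counting interval 10.3 to 17.02) in replicate 1 and 34.46 (29.4 to 40.2) in replicate 2. The region in Nfyc (chromosome 4, 120825196 to 120826200) had folds of 18.5 (14.2 to 23.8) and 31.5 (26.2 to 37.6) and lay inside the gene, 5881 bp from its nearer end. At Srcap (chromosome 7, 127511852 to 127512919) the folds were 12.6 (9.45 to 16.4) and 19.2 (15.1 to 24.0). The best-ranked Epc1 region (chromosome 18, 6489904 to 6491331) had folds of 14.2 and 23.9 and lay in the gene interior, 25491 bp from an end. Kmt2a had folds of 17.3 and 13.1, and Kmt5b of 12.9 and 18.3.

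Also among these 20 regions, that of Rbm39, a splicing-associated RNA-binding protein, had folds of 15.7 in replicate 1 and 11.6 in replicate 2. Clk1, a kinase of splicing factors, had 9.96 and 17.4, Ddx39b, an RNA helicase, 12.02 and 9.64, Pcbp1, an RNA-binding protein, 9.84 and 21.6, and Serbp1 10.3 and 15.3. Eif4a2, a translation initiation helicase, had 10.3 and 16.3. The nuclear pore gene Seh1l had 17.3 and 18.5, the phosphatase subunit gene Ppp1r10 19.0 and 12.9, and Ywhae, a 14-3-3 protein, 11.4 and 12.4. Zc3h4 had 15.1 and 15.98, Hexim2 18.2 and 18.8, and Efcab2 12.3 and 11.9. The other two of the 20 regions had low folds on a high background. One spans Rn18s-rs5, an rRNA pseudogene on chromosome 17 (39843129 to 39848812), with folds of 3.03 and 6.76 over backgrounds of 105 and 127 reads; the other lies in Zc3h7a on chromosome 16 (11143936 to 11144277), with folds of 3.77 and 6.78 over backgrounds of 33.8 and 42.7 reads. The lowest background in the lists was 2.24 and 2.65 reads.

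Of the fixed gene lists, 3 held shared regions at gene ends more often than other protein-coding genes, of which about 16% did. Ribosomal protein genes did so in 33 of 50 cases (66.0%, 95% interval 51.2 to 78.8; odds ratio 10.3, 5.56 to 19.7; Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 2.17e-14). By the worse of its ranks in the lists, Rpl24 came first, with folds of 10.2 (7.05 to 14.2) in replicate 1 and 7.36 (5.36 to 9.89) in replicate 2, and regions also lay at Rpl18 (6.72 and 10.2) and Rps18 (6.41 and 5.96). Of 44 oxidative phosphorylation genes, which encode subunits of the mitochondrial respiratory chain, 26 held a region (59.1%, 43.2 to 73.7; odds ratio 7.64, 4.02 to 14.8; Fisher's exact test, adjusted p = 5.15e-10). Ndufb6 (folds 9.56 and 8.19), Ndufs3 (7.71 and 10.2), Ndufs7 (6.16 and 7.54) and Ndufb5 (7.56 and 5.31) were among them. The region counted for Rpl18 lay 2564 bp from its end. In these tests the other protein-coding genes included families with no region, such as 1109 olfactory receptor genes. No background of expressed genes was used, so the odds ratios do not compare a list with expressed genes alone.

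Genes of the complexes in which RUVBL1 and RUVBL2 take part held shared regions in 20 of 35 cases (57.1%, 39.4 to 73.7; odds ratio 7.04, 3.42 to 14.8; Fisher's exact test, adjusted p = 1.27e-07). They included subunits of INO80 (Ino80, Ino80c, Ino80d, Ino80e, Actr8, Mcrs1, Tfpt and Yy1), of SRCAP (Srcap and Znhit1) and of the TIP60 acetyltransferase complex (Kat5, Ep400, Trrap, Epc1, Epc2, Brd8, Ing3 and Morf4l1). Epc2 had folds of 10.6 (7.57 to 14.6) in replicate 1 and 12.1 (8.996 to 15.98) in replicate 2, and Morf4l1 of 8.92 and 11.1. Ruvbl2 itself held no peak within 3 kb in either list, the nearest lying 26308 bp away in replicate 1. Ruvbl1 held no shared region; replicate 2 alone listed a peak 2621 bp from its end with a fold of 3.08 (1.87 to 4.83). With the top 1000 peaks of each list only, the ribosomal protein (adjusted p = 0.0791) and oxidative phosphorylation (adjusted p = 0.154) lists no longer passed Fisher's exact test. The RUVBL complex list still passed Fisher's exact test, with 8 of 35 genes (odds ratio 9.996, adjusted p = 4.64e-05).

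Synaptic genes did not differ detectably from all other protein-coding genes in the shared regions. A difference from expressed genes alone was not tested. Of 32 genes of the glutamatergic postsynapse, 4 held a region (12.5%; odds ratio 0.75, 95% interval 0.191 to 2.15; Fisher's exact test, adjusted p = 0.809): Dlg1, a scaffold protein (folds 4.62 and 4.84), Grik5, a kainate receptor subunit (4.27 and 4.43), Dlg2 (3.56 and 3.504) and the scaffold Shank1 (3.59 and 6.86). Of the 32 genes, 5 held a peak in replicate 1 and 9 (28.1%) in replicate 2, with genes of both lists counted in each. Neither share passed Fisher's exact test. Of 30 genes of presynaptic release, 5 held a shared region (16.7%; odds ratio 1.05, 0.314 to 2.80; Fisher's exact test, adjusted p = 0.809). They included Vamp2, the vesicle SNARE (folds 4.51 and 5.51), Nsf, which disassembles SNARE complexes (6.40 and 4.87), Sv2a (4.198 and 4.02) and Ppfia3. The Sv2a region lay 2177 bp from its end. With each region given to its nearest gene end only, 3 of the 30 presynaptic genes held one (odds ratio 0.766). The rest of the 5 had a region nearer the end of another protein-coding gene. Of the 32 glutamatergic genes, 4 still held one. In the longer list of replicate 2 alone, 15 of the 30 presynaptic genes held a peak (50%, against 30.4% of all protein-coding genes; odds ratio 2.29; Fisher's exact test, adjusted p = 0.0437), and 7 of 30 did in replicate 1. None of the 18 GABAergic synapse genes held a shared region at an end, which allows a share of up to 16.7% (adjusted p = 0.197 by Fisher's exact test); Gabrb1 and Gphn held one in the gene interior.

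Of 40 appetite and hypothalamic peptide genes, 2 held a shared region: Pomc, the precursor of the appetite-lowering peptide α-MSH, and Ntrk2, the receptor of BDNF. The Pomc region (chromosome 12, 3959940 to 3960523) had folds of 6.77 (4.31 to 10.2) in replicate 1 and 6.60 (4.32 to 9.69) in replicate 2. It lay inside the gene (3954945 to 3960643), 412 bp from the end with the higher coordinate. Strand was not given, so this end was not shown to be the transcription start. Ntrk2 had folds of 4.51 and 6.86. Neither list held a peak within 3 kb of Mc4r, Sim1, Oxt, Avp, Crh, Trh, Agrp or Npy. The nearest peak to Oxt lay 10447 bp away and the nearest to Trh 27257 bp. The chromatin was that of the hypothalamus and not of chosen neurons. A missing peak therefore does not show that binding was absent in a small share of the cells. The list as a whole (5%; odds ratio 0.276, 0.0323 to 1.07) did not pass Fisher's exact test on shared regions (adjusted p = 0.197), and was below other genes in each library alone (2 of 40 genes and adjusted p = 0.0445 in replicate 1, 3 of 40 and 0.00267 in replicate 2).

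Markers of the other cell types of this tissue held almost no shared regions. No gene of the astrocyte, microglia or endothelial and mural lists (14 genes each) and none of the 18 oligodendrocyte markers held one, which allows shares of up to 21.4% and 16.7%. Among 13 ependymal and tanycyte markers, Col23a1 held one (folds 4.93 and 4.34), and among 24 liver genes, Apoa2 did (5.14 and 4.14). Both regions lay nearer the end of another protein-coding gene. With each region given to its nearest gene end only, 0 of 13 ependymal and tanycyte markers and 0 of 24 liver genes held one. With lists this short, none of these lists passed Fisher's exact test on shared regions (adjusted p from 0.197 to 0.807). In replicate 2 alone, the oligodendrocyte (1 of 18), microglia (0 of 14), endothelial and mural (0 of 14) and liver (1 of 24) lists were below other genes, with adjusted p of 0.0351, 0.0162, 0.0162 and 0.00813 by Fisher's exact test, while 3 of 14 astrocyte markers held a peak. None of 1109 olfactory receptor genes held a shared region, which allows up to 0.271% (Fisher's exact test, adjusted p = 1.01e-85). These genes lie in clusters and are not independent, although the limit and the p treat them as if they were. Immediate early genes held regions in 5 of 22 cases (22.7%; Fisher's exact test, adjusted p = 0.469), namely Nr4a3 (folds 6.09 and 7.96), Fosl2 (5.24 and 4.26), Dusp1 (4.26 and 3.98), Jun (4.01 and 5.37) and Jund. Of 64 replication-dependent histone genes, 4 did (6.25%; Fisher's exact test, adjusted p = 0.122): H1f2, H2ac18, H3c14 and H4f16. H2ac18 and H3c14 share 1 region.

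**Figure D2:**
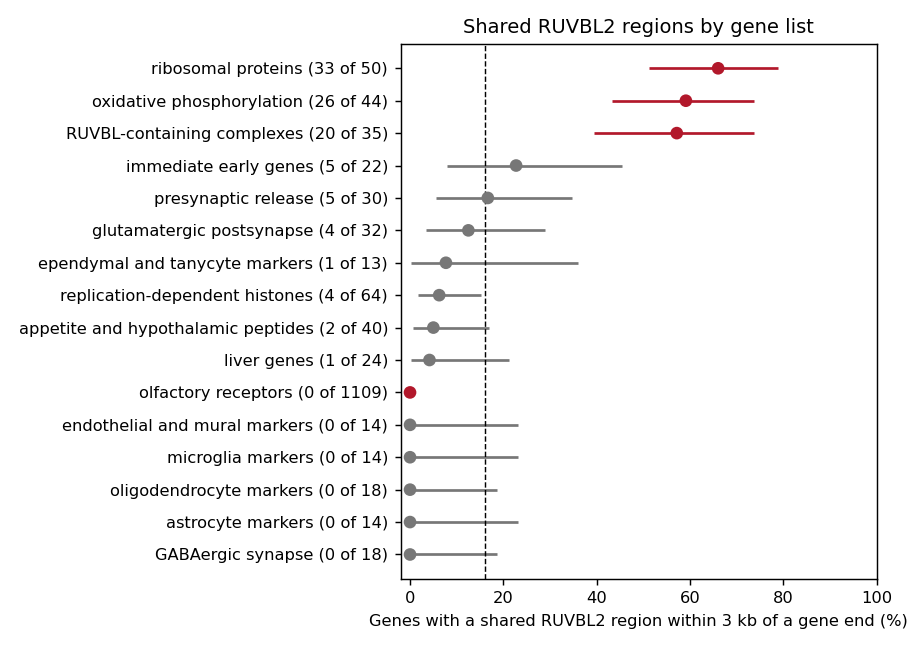
Percent of the genes of each fixed list with a shared RUVBL2 region within 3 kb of a gene end (points), with exact 95% intervals (lines). The dashed line marks all protein-coding genes (15.99%), and red marks lists with an adjusted p under 0.05 by Fisher's exact test: ribosomal proteins at 66.0%, oxidative phosphorylation at 59.1% and RUVBL-containing complexes at 57.1% lie above the line and olfactory receptors at 0% below it.

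In gene bodies widened by 3 kb, ribosomal protein genes held shared regions in 34 of 50 cases (against 0.677 ± 0.813 genes under random placement, SD), oxidative phosphorylation genes in 28 (0.960 ± 0.960), RUVBL complex genes in 20 (1.62 ± 1.22), immediate early genes in 5 (0.519 ± 0.700) and olfactory receptor genes in 0 (12.8 ± 3.59). Each of these 5 lists had an adjusted permutation p of 0.00064, and the other 11 missed the threshold. Random placement keeps gene length but puts only 8.78% of regions near gene ends, so short genes can exceed it without exceeding other genes: immediate early genes did not differ detectably from other genes at their ends, and 4 histone genes held a region against 0.452 ± 0.935 placed, with an odds ratio of 0.349 against other genes at their ends. The olfactory receptor list no longer passed with placement within 50 kb (adjusted permutation p = 0.267).

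Of the genes of the glutamatergic postsynapse, 4 held a region in their widened bodies against 8.53 ± 2.03 placed (adjusted permutation p = 0.0960). This difference depended on the setting. At a −log10 q of at least 5 and with 50% overlap the list passed as lower (adjusted permutation p = 0.0080 and 0.0331), with summits within 250 bp it did not (0.279), and with placement within 50 kb the difference was −0.112 genes (adjusted permutation p = 1).

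Most peaks of replicate 1 were found again in replicate 2. Of its 3943 peaks, 3159 (80.1%, 95% interval 78.8 to 81.4) overlapped a peak of replicate 2, against a mean of 0.299% and a maximum of 0.634% over 10000 random placements (one-sided permutation p = 0.0001, the smallest these can give). Of the 6403 peaks of replicate 2, 3127 (48.8%) overlapped a peak of replicate 1 (one-sided permutation p = 0.0001). Random placement does not keep peaks near gene ends, where 88.8% of replicate 1 and 87.4% of replicate 2 peaks lay. Unrelated lists that both favour gene ends could exceed it too, and overlap beyond that was not tested. Replicate 2 had peaks near the ends of 30.4% of all protein-coding genes. Summits of overlapping peaks lay a median of 94 bp apart. In replicate 2, when the list was divided into 4 parts by p, 79.8% of the part with the smallest p was found again and 26.1% of the part with the largest p. Peaks listed by replicate 2 only had a median fold of 4.39 and a median pileup of 19 reads, against 5.35 and 25 reads for its shared peaks. Restricted to the top 1000 peaks of each list, 49.8% of those of replicate 1 were among those of replicate 2.

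**Figure D3:**
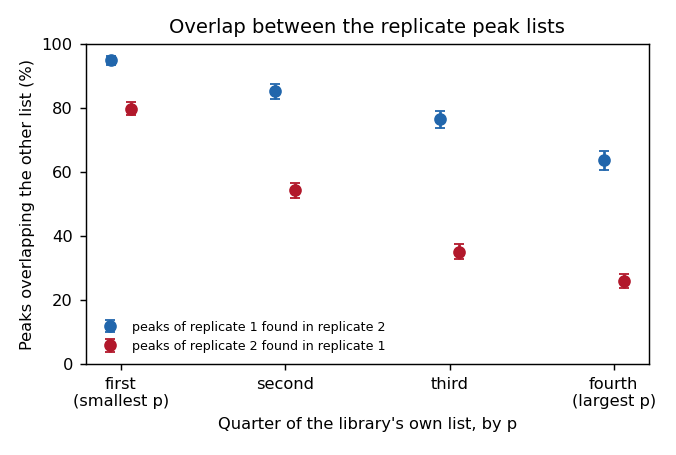
Percent of peaks that overlap a peak of the other list by at least 1 bp, by each of 4 parts of the library's own list ordered by p, with exact 95% intervals. In replicate 1 (blue) the share runs from 94.9% in the part with the smallest p to 63.7% in that with the largest, and in replicate 2 (red) from 79.8% to 26.1%.

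Chromosomes differed in the number of peaks. Chromosome 11 held 1.81 times the peaks its length would give in replicate 1 and 1.90 times in replicate 2, but 1.10 and 1.16 times the number expected from its protein-coding genes. Chromosome X held 18 peaks in replicate 1 (0.0725 times the number expected from its length, 95% interval 0.0430 to 0.114) and 69 in replicate 2 (0.171 times, 0.133 to 0.216); from its genes the ratios were 0.103 and 0.244. The exact binomial p by length was 4.86e-84 in replicate 1 and 6.39e-98 in replicate 2. The tissue came from male mice, whose cells carry a single X chromosome. The number of peaks per chromosome departed in both libraries from chromosome length and also from gene number (permutation p = 0.0001 from 10000 random draws in each case, the smallest they can give). By gene number, chromosome 7 held 0.704 times the expected peaks in replicate 1 and 0.798 times in replicate 2. No peak lay on the mitochondrial genome, 1 peak of replicate 2 lay on Y, and each list had 2 peaks on unplaced scaffolds.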

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

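Alternatives with the nearest gene end only, without regions at high background, without chromosome X, and by gene number were chosen after seeing the data. Of 256 alternative values, 229 were labelled as kept, including all for list overlap, region position and chromosome X. Kept meant the same direction and side of the threshold. Counts of lists have neither: 6 against 4 and 7 against 5 were labelled as kept. Single lists in gene bodies were not among the 256. The share near a gene end ranged from 81.7% with a window of 1 kb to 92.9% with the ends of all annotated genes, and was 87.4% without replicate 1 and 88.8% without replicate 2. The number of lists past the threshold at gene ends (4) was 2 with the top 1000 peaks of each list, 11 with the union of both lists, and 6 to 10 with one replicate left out; for gene bodies (5) it was 3 with the top 1000 peaks, 4 with placement within 50 kb, 6 with 50% overlap, 7 with the union, and 5 to 7 with one replicate left out. With the top 1000 peaks, the ribosomal protein list (odds ratio 3.73) and the oxidative phosphorylation list (3.35) kept their direction and lost the threshold on fewer regions. With the union of both lists, those newly past it were presynaptic release (odds ratio 2.29), appetite genes (0.162), oligodendrocyte (0.118), microglia (0) and endothelial (0) markers, liver genes (0.0869) and histones (0.509). Of these, replicate 2 alone also called presynaptic release (2.29), appetite genes (0.185), oligodendrocyte (0.135), microglia (0) and endothelial (0) markers and liver genes (0.0994), and replicate 1 alone called appetite genes (0.219) and histones (0.352), against odds ratios of 1.27 for presynaptic release and 0.181 for liver genes in replicate 1 and 0.527 for histones in replicate 2, which missed it. The cause of these differences was not tested. Lists that missed the threshold changed side of 1 at gene ends as follows. Presynaptic release had odds ratios of 0.400 at a −log10 q of at least 5, 0 with the top 1000 peaks, 0.950 with a window of 1 kb and 0.766 with the nearest gene end only. Immediate early genes had 0.617 with a window of 1 kb, and the glutamatergic list 1.51 with the ends of all annotated genes. For gene bodies, in genes with a region minus genes expected from placement, the sign changed for these lists. Presynaptic release gave 0.814 with placement within 50 kb and 7.32 with the union, and 0.200 to 6.91 with one replicate left out. GABAergic genes gave 0.423 within 50 kb. Ependymal markers gave −0.386 at the stricter q, −0.158 with the top 1000 peaks, −0.646 with summits within 250 bp, −0.200 within 50 kb, −0.343 with the union and −0.266 without replicate 1 (0.119 without replicate 2). Appetite genes gave −0.264 with the top 1000 peaks, −0.410 with the union and −0.0815 without replicate 1 (0.0089 without replicate 2). Liver genes gave −0.129, −0.643 and −0.480 in the same order (0.0609 without replicate 2). Histones gave −0.0578 with the top 1000 peaks, and astrocyte markers 1.013 with the union and 1.17 without replicate 1 (−1.28 without replicate 2). Only presynaptic release with the union (adjusted permutation p = 0.00411) and without replicate 1 (0.00457) passed the threshold after such a change; placement does not keep regions at gene ends, so this does not compare the list with other genes. The immediate early list lost its gene body call at the stricter q (adjusted permutation p = 0.122) and with the top 1000 peaks (0.487), and the olfactory receptor list lost its own within 50 kb (0.267) and with the top 1000 peaks (0.487). The glutamatergic list passed as lower at the stricter q and with 50% overlap only. Histones passed placement as higher with the union (11.9 genes, adjusted permutation p = 0.00107) and without replicate 1 (11.1 genes, 0.000533), although the union called them lower than other genes at gene ends. Of the 52 named regions, 36 remained at the stricter q, 29 with the top 1000 peaks, 50 with 50% overlap and 45 with summits within 250 bp. Of the synaptic and appetite regions given by gene, those of Nsf and Pomc remained at the stricter q and the others were lost, so the presence of the others rests on the deposited threshold. Planned tests that need a genome sequence, strand or exons were not run. No paired analysis was possible because no input values were used here. Depth limits the weaker peaks: the lowest summit pileups listed were 10 and 11 reads.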

Other observations

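The tests of families by symbol and gene types, of synaptic against marker genes, of ribosomal protein pseudogenes, of the gene content of X and of the background at loci with a low fold were chosen after the results were seen. Of 143 families of at least 15 protein-coding genes that share the letters of their symbol, 26 held shared regions at gene ends more often than other genes and 13 less often (Fisher's exact test, Benjamini-Hochberg adjusted over the families). By Fisher's exact test, the higher ones included translation initiation factors (Eif, 24 of 56 genes, adjusted p = 3.9e-05), DEAD-box helicases (Ddx, 18 of 37, 7.4e-05), ubiquitin-conjugating and related enzymes (Ube, 20 of 42, 3.9e-05), mitochondrial ribosomal proteins (Mrpl, 21 of 49, 0.000129), general transcription factors (Gtf, 12 of 23, 0.000933), RNA-binding motif proteins (Rbm, 15 of 38, 0.00363) and nucleoporins (Nup, 10 of 21, 0.00494). Zinc finger genes named Zfp held regions in 84 of 397 cases (21.2%, Fisher's exact test, adjusted p = 0.0273). The lower ones included vomeronasal receptors (Vmn, 0 of 352, which allows up to 0.852%), cytochromes P450 (Cyp, 1 of 99), keratin-associated proteins (Krtap, 0 of 56, up to 5.36%) and beta-defensins (Defb, 0 of 42, up to 7.14%). Many of these families lie in clusters, so their genes are not independent.

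Within 500 bp of a gene end, 2660 of 21779 protein-coding genes (12.2%) held a shared region, against 336 of 12639 lncRNA genes (2.66%), 12 of 476 transcribed pseudogenes (2.52%), 26 of 1228 miRNA genes (2.12%), 7 of 403 tRNA genes (1.74%), 9 of 1330 snoRNA genes (0.677%), 1 of 997 snRNA genes, 0 of 62 rRNA genes (exact 95% interval up to 5.78%) and 8 of 9854 other pseudogenes (0.0812%). Of the 327 shared regions not found within 3 kb of a protein-coding gene end, 107 lay within 3 kb of an end of another annotated gene. The 327 include the region on an unplaced scaffold, for which no distance was measured.

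Ribosomal protein, respiratory chain and RUVBL complex genes held regions in 57.1% to 66.0% of cases, while the glial, ependymal, vascular and GABAergic lists pooled held them at 1 of 91 genes. In the libraries alone, this pool held peaks at 1 of 91 genes in replicate 1 and 7 of 91 in replicate 2. Synaptic genes did at 12 of 62 and 24 of 62, and all protein-coding genes at 19.4% and 30.4%. Counting regions of neighbouring genes is argued against as the whole cause of the 3 high shares. All 3 lists stayed past the threshold when each region was given to its nearest gene only (Fisher's exact test, largest adjusted p = 9.94e-07). The counts were then 29 of 50 ribosomal protein, 21 of 44 respiratory chain and 17 of 35 RUVBL complex genes, against 12.6% of other genes. Neighbours may thus account for a part of the shares. Reads of processed gene copies placed on the ribosomal protein genes stay open: 3 of 300 of their pseudogenes held a region (upper 95% bound 2.89%), but misplaced reads would be missing there too, and reads from mRNA were not tested. One hypothesis is that marker genes are used in too few cells of a whole hypothalamus to give a peak; it cannot be told apart from a preference for a kind of promoter, since the pooled comparison (9 of 62 synaptic genes against 1 of 91, Fisher's exact p = 0.00136) restates shares already seen and its marker pool includes GABAergic synapse genes, which are not confined to rare cells. Pull-down of open promoters without RUVBL2 stays open too, because no control antibody or cells without RUVBL2 were analysed here.

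Chromosome X held few peaks in both libraries. A single copy of X in male cells is argued against as the whole cause. Each autosomal summit pileup was thinned by chance to 50% of its reads. After thinning, 32.2% of autosomal peaks in replicate 1 and 53.3% in replicate 2 still reached the lowest listed −log10 p (4.48 and 4.21). X had only 9.80% (95% interval 5.81 to 15.5) and 23.3% (18.1 to 29.4) of the autosomal number of peaks per gene. The comparison takes X-linked sites to have the pileups of autosomal ones per copy, and a lower copy number may still account for a part. The gene content of X is another explanation: of the ribosomal protein, respiratory chain and RUVBL complex genes, 1 of 4 on X and 78 of 125 on autosomes held a region (Fisher's exact p = 0.298). Only 0 of 4 could have passed (exact p = 0.0209), and a p that misses the threshold does not show equal shares, so this stays open.

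Some peaks had a very small p and a low fold. At the rRNA pseudogene on chromosome 17 the background recovered from the lists was 46.8 times the lowest background in replicate 1 and 48.1 times in replicate 2, and at Zc3h7a 15.05 and 16.1 times. A peak in Lars2 (chromosome 9, 123461846 to 123462177; fold 5.996, pileup 158 reads), listed by replicate 2 only, had 9.65 times the lowest background. Many genomic copies collapsed onto one reference locus is a candidate explanation that stays open at all 3 loci, because the background follows from the same fold and p that single these peaks out, and no copy number was measured. No biological explanation was tested for these loci.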
